A study of Mus musculus with 13 samples.

How the data were processed

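Total RNA of mouse ESC lines was labelled with Cy3 and hybridised to Agilent 1-colour gene expression arrays, per the labels. The labels name 4 groups, control and OHT cultures of the 2ac and of the 2abc genotype, each with 3 lines that were grown both ways. Per the labels, the lines came from C57Bl/6 mice and were cultured on gelatin in serum-free N2B27 medium with LIF and inhibitors of MEK and GSK3, and RNA was purified on RNeasy columns. For the control culture of 2ac line cl4 the array of the second hybridisation was analysed. The OHT culture of that line was on 2 arrays, and these were averaged after normalisation and counted as 1 sample. They correlated at r = 0.994 with a median absolute difference of 0.105 log2, while the OHT samples of lines cl4 and cl5 on 1 slide correlated at 0.993 with a median absolute difference of 0.143.

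The spot intensity values were made with Agilent Feature Extraction 11.0.1.1, per the file headers, which subtracted the background and removed spatial trends within each array without scaling between arrays. Of 59305 non-control spots per array, 184 to 253 carried an outlier flag of that software and were left out, control spots were left out, and spots of the same probe were averaged, giving 55681 probes. The log2 values of the authors' deposited table of the whole series were used as an alternative. It held 21283 lines for 19371 probe identifiers, 1912 of them repeats, which were averaged. Its columns correlated with log2 of the median spot intensity of the same array at r of 0.999 to 1.00, and with log2 of the background-corrected signal used here at 0.994 to 0.998, and had medians of 10.48 to 10.57, so its scale was taken from that comparison to be log2. Per the submitters' processing notes limma was used on it, with no version. The authors labelled the table loess, and how that normalisation was done and which filter was used are not given in the sources used here. It held 0 columns outside the 13 arrays.

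For every array, the 75th percentile of log2 processed signal was subtracted from log2 processed signal. That percentile corresponded to signals of 460 to 595, with 50.1 to 63.9% of probes well above background and 0 saturated. Probes were named through the accession in the array's own annotation, matched without version to a RefSeq gene table of assembly GRCm38.p6. Of 28066 probes with a RefSeq transcript accession 27640 matched, and 27656 probes carried 1 symbol (20972 symbols). The array design gives positions in assembly mm9, so no coordinates are printed, and the table served only for names, chromosomes and the order of genes along a chromosome. A probe was kept if it was well above background on every array of at least 1 of the 4 groups (30675 probes), and the probe with the highest mean over all samples stood for a gene. This left 22967 features, 14661 with a gene symbol and 8306 named by accession or probe. Other probes of called genes moved the same way for 94.0% in 2ac, 94.0% in 2abc and 92.2% over the 6 lines, and 0, 7 and 21 of them were called in the opposite direction.

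Changes were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) on all 12 samples, with the ESC line as a fixed block and the OHT effect of each genotype as a coefficient. The 4 comparisons were the effect in 2ac, the effect in 2abc, their mean over the 6 lines, and the 2abc effect minus the 2ac effect. All groups shared 1 estimate of the spread, with 4 residual degrees of freedom per gene. P-values were adjusted over all genes by the method of Benjamini and Hochberg, and an adjusted p under 0.05 was called. The pairing of cultures comes from the design, since control and OHT samples with the same number are the same ESC line. As a check, deviations from the group means of the 2 samples of a line correlated at 0.16, 0.46 and 0.50 in 2ac lines cl4, cl5 and cl6 and at 0.03, -0.02 and -0.01 in 2abc lines cl280.4, cl324.9 and cl324.13, and in 3 of the 6 lines (cl280.4, cl5 and cl6) the own partner correlated best. The arrays lay on 3 slides with 2, 3 and 8 arrays. Each line's control and OHT arrays shared a slide, except the first hybridisation of the OHT sample of cl4, so apart from that array the line as a block also takes up the slide, and the slide as the block in place of the line was an alternative.

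Gene lists were fixed before the data were examined, as were the groups, the tests, the rule for naming genes and all other settings except those said below to have been added. There were 28 lists: the Jmjd2 family, H3K9 and H3K36 methylation machinery, KRAB zinc-finger and retroelement-silencing genes, core and naive pluripotency, formative and primed, neural, mesoderm, endoderm, trophectoderm, germline, 2-cell-like, imprinted and Hox genes, p53 targets, mitosis, DNA replication, interferon, glycolysis and hypoxia, sterol synthesis, ERK and Wnt targets, ATF4 stress, ribosomal protein and reference genes, sex-linked genes, and markers of fibroblasts and of blood cells as other cell types. The 26 lists with at least 5 measured genes were tested with camera of limma, which compares a list's genes with all others, at its preset correlation of 0.01, with adjustment over the 26 lists of a comparison. Over the 4 comparisons 42 such tests passed, and 0 did with the correlation estimated from the residuals. The residuals leave 4 degrees of freedom for that estimate. In 1000 random lists of 20 genes, 2.4 to 3.8% had p under 0.05 at the preset correlation and 0.1 to 0.3% at the estimated one. Genes drawn at random need not vary together as related genes may. These shares therefore do not give the error of either test for lists of related genes. The rotation test fry, which asks whether a list's own genes moved on balance one way, passed 38 times. A range over preset-camera alternatives is one over the other settings with camera at its preset correlation, and fry and the estimated correlation are given apart from it. The genes named are the 3 targeted ones, for each comparison the 10 largest rises and 10 largest falls by measured signal among called genes with the same sign in every line, leaving out names that are not gene symbols, and up to 4 members of a list with the smallest p. Where none passed, the 5 with the smallest p are given as not passing. A gene that no array of 1 group measured well above background has only a bound for its fold. Setting list members to their bound, and leaving out those below background in both groups, moved list medians by at most 0.08 and changed the sign of 0 of 52.

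The fit was tested on simulated data of 22955 genes with the real spread, in 5 sets with 200 changed genes each. At a log2 change of 1, 55.4% were recovered in 2ac, 57.2% in 2abc, 75.0% for the mean and 31.4% for the difference. At a log2 change of 2 these were 86.4, 85.6, 92.6 and 70.0%. False calls made up 4.87, 6.21, 6.14 and 4.88% of calls. A list of 20 genes shifted by 0.5 in these sets had p under 0.05 in 5 of 5 sets of each comparison, at the preset and at the estimated correlation. The simulated genes varied independently of each other, which real genes need not do. The share of changed genes was also set and not that of the real fits. The adjusted p depends on that share, so these rates need not hold there. Alternatives were a random or no block for the line, the slide as the block, scaling by the median, quantile or cyclic loess normalisation, the authors' deposited table, no filter on dim probes or a filter on all 13 arrays, every probe tested, only the 2 groups compared, array weights, a trended and robust prior, either array of the OHT sample of cl4, other thresholds and each line left out. Added after the data were seen were normexp on the median spot and local background intensities, with an offset of 50, the genes of chromosomes 3 and X left out, and lines cl6 and cl280.4 both left out. Chromosome medians were set against 10000 random gene lists matched on mean expression. Other splits of the samples into groups were refitted in the same way. The brightest genes in a test are the 1 in 3 with the highest mean signal.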

Results

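Gene expression was measured on 1-colour Agilent arrays in mouse embryonic stem cell (ESC) lines in which genes of the Jmjd2 (Kdm4) family, demethylases of histone H3 lysines 9 and 36, can be deleted. Lines of both genotypes carried a tamoxifen-inducible Cre recombinase (CreERT2) at the Rosa26 locus. The 2ac lines cl4, cl5 and cl6 held floxed alleles of Jmjd2a and Jmjd2c (Kdm4a and Kdm4c), and the 2abc lines cl280.4, cl324.9 and cl324.13 held floxed Jmjd2b (Kdm4b) as well. Every line was sampled from an untreated culture (control) and from a culture that had received 500 nM of the tamoxifen metabolite OHT for 12 days and was harvested 6 days later. The cells were kept without serum in LIF with inhibitors of MEK and GSK3, which hold ESCs in the naive state. There were thus 4 groups of 3 samples. The OHT sample of 2ac line cl4 was hybridised on 2 arrays that were counted as 1 sample, giving 12 samples from 13 arrays. On each array 50.1 to 63.9% of 55681 probes lay well above background and 0 were saturated. The lines of a genotype are described as independently established, and the p-values rest on the spread between 3 lines per genotype, which limits the precision. Lines cl324.9 and cl324.13 share the first number of their names, and their changes correlated at 0.752, against 0.530 and 0.576 with cl280.4. The changes of 2ac lines cl4 and cl5, whose names share no number, correlated at 0.749, against 0.527 and 0.539 with cl6. Whether these lines have a common origin is not given in the sources used here, and the p-values take the lines as independent. Changes are OHT minus control within a line, on the log2 scale, with their standard error (SE).

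The targeted genes were examined first. Kdm4c (chromosome 4, probe A_55_P2053206) fell in both genotypes, with a log2 change of -2.90 in 2ac (SE 0.25, limma adjusted p = 0.00502) and -3.21 in 2abc (SE 0.25, adjusted p = 0.00412), which left 13.4% and 10.8% of the control signal. It fell in each of the 6 lines, with changes of -3.66 to -2.27 in the 2ac lines and -3.28 to -3.15 in the 2abc lines. Kdm4b (chromosome 17, probe A_55_P2028064) fell in 2abc to 21.4% of control (log2 change -2.23, SE 0.19, adjusted p = 0.00451, per line -2.58 to -1.68). In 2ac, where it was not targeted, its change was 0.12 (SE 0.19, adjusted p = 0.735, per line -0.04 to 0.34). Kdm4a (chromosome 4, probe A_52_P281209) fell less far, to 59.8% of control in 2ac (log2 change -0.74, SE 0.09, adjusted p = 0.0109) and to 62.7% in 2abc (-0.67, SE 0.09, adjusted p = 0.0114), and was lower after OHT in each of the 6 lines (-0.87 to -0.54). The Kdm4a call was lost in some fits with fewer samples. Its adjusted p in 2ac was 0.0702 without line cl4 and 0.0726 without line cl5, in a range of 0.000473 to 0.0726 over all alternatives. In 2abc it was 0.0685 without line cl324.9, 0.0790 without line cl324.13 and 0.0558 with the 2abc samples alone, in a range of 0.000646 to 0.0790. The position of these probes relative to the deleted exons is not given in the sources used here, so a remaining signal does not measure remaining intact transcript. A second Kdm4a probe (-1.07 in 2ac, adjusted p = 0.0714, and -0.69 in 2abc, adjusted p = 0.163) was well above background on 5 arrays only, and the Kdm4d probe on 0 arrays. In log2 relative to the 75th percentile of the array, Kdm4a went from a control mean of 2.77 ± 0.02 (SD, n = 3) to 2.03 ± 0.07 in 2ac and from 2.75 ± 0.01 to 2.08 ± 0.18 in 2abc. Kdm4c went from 2.17 ± 0.03 to -0.74 ± 0.67 in 2ac and from 2.38 ± 0.22 to -0.83 ± 0.25 in 2abc, and Kdm4b in 2abc from 2.30 ± 0.43 to 0.07 ± 0.09.

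**Figure D1:**
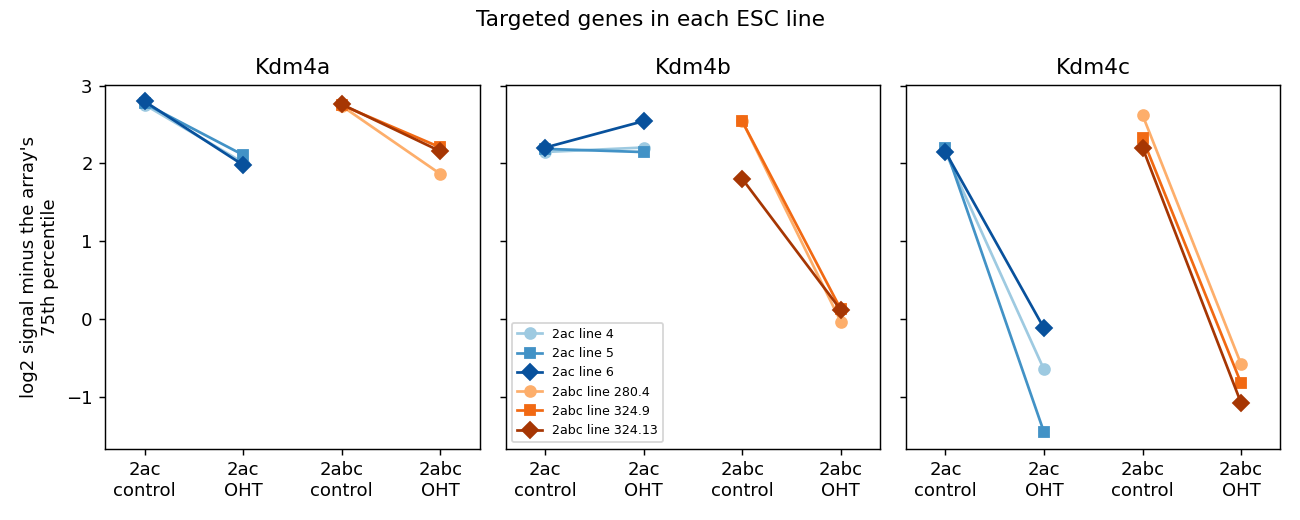
Log2 signal of Kdm4a, Kdm4b and Kdm4c, relative to the 75th percentile of each array, in the control and OHT culture of each ESC line, with 1 line joining the 2 cultures of an ESC line. Kdm4c fell in all 6 lines (log2 change -3.66 to -2.27), Kdm4b fell in the 3 2abc lines (-2.58 to -1.68) and not in the 2ac lines (-0.04 to 0.34), and Kdm4a was lower after OHT in all 6 lines (-0.87 to -0.54).

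Besides the targeted genes, the cultures differed by chromosome and by line. The 665 genes of chromosome 3 had a median change of 0.24 over the 6 lines, above the highest median of 10000 random gene lists of matched expression (0.05). The median was 0.16, 0.33 and 0.20 in 2ac lines cl4, cl5 and cl6, and 0.11, 0.36 and 0.40 in 2abc lines cl280.4, cl324.9 and cl324.13. Over the 6 lines 39.4% of chromosome 3 genes rose and 5.71% fell. On chromosome 4, which holds Kdm4a and Kdm4c, 13.2% of 960 genes rose and 24.6% fell. Their median change was -0.06 over the 6 lines and -0.11 to -0.02 by line, and was not set against random lists. The 535 genes of the X chromosome had a median change of 0.71 in 2ac line cl6, against -0.02 to 0.08 in the other 5 lines. Line cl280.4 changed less than the other lines. The SD of its changes over all genes was 0.489, against 0.580 to 0.790 elsewhere, and the slope of its changes on those of the other 2abc lines was 0.400.

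**Figure D2:**
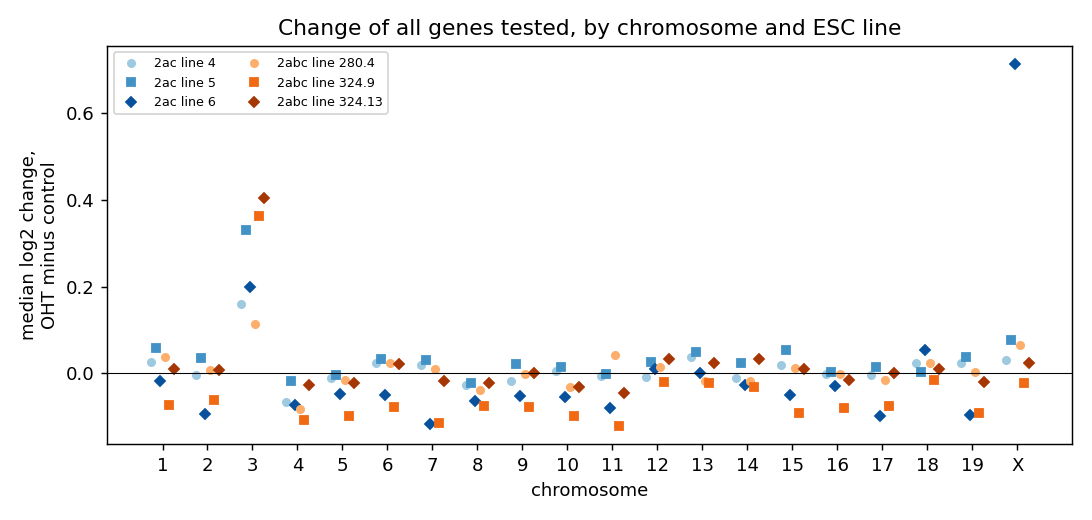
Median log2 change (OHT minus control) of all genes tested on each chromosome, with 1 point per ESC line. Chromosome 3 lies above 0 in all 6 lines (0.11 to 0.40), and the X chromosome lies at 0.71 in 2ac line cl6 and between -0.02 and 0.08 in the others.

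Deletion of Jmjd2a and Jmjd2c together was addressed by comparing OHT with control in the 2ac lines. Wnt8a, which encodes a Wnt ligand of the primitive streak, rose at least 12.3-fold (adjusted p = 0.00359) and the sialyltransferase gene St8sia3 rose at least 12.5-fold (adjusted p = 0.00037). For genes such as these, which no array of the dimmer group measured above background, the fold is a lower bound. It was taken against the lowest signal among probes well above background on each of those arrays, or the gene's own signal where that was higher. A probe can exceed that lowest signal without being well above background, so the bound is approximate. The genes named were chosen by measured signal, so the order among bounded genes is not known. The proneural transcription factor gene Atoh1 rose at least 3.38-fold, the aldehyde dehydrogenase gene Aldh1a7 at least 2.97-fold and Tcim at least 3.39-fold (adjusted p = 0.00633, 0.00592 and 0.00858), the last 2 measured on 3 of the 4 OHT arrays. Ccnd2, a D-type cyclin, rose by 3.94 (SE 0.41, adjusted p = 0.0071), Lrrk2, a kinase mutated in familial Parkinson disease, by 3.49 (SE 0.36, adjusted p = 0.00707) and Insm1, a zinc-finger factor of neuroendocrine cells, by 3.53 (SE 0.49, adjusted p = 0.0138). Gna14, a G-protein alpha subunit, and Btla, an inhibitory lymphocyte receptor, were the others chosen among the rises (3.88 and 3.69, adjusted p = 0.00405 and 0.0181), each above background on 1 of 3 control arrays, while Ccnd2 and Insm1 were so on 2 of 3. A second probe of Lrrk2 had a change of 1.86 and did not pass (adjusted p = 0.156).

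Among the genes that fell in the 2ac lines, Mrgprd, a receptor of sensory neurons, was at least 5.70-fold lower (adjusted p = 0.00359) and Pdgfrb, a receptor for platelet-derived growth factor, at least 3.43-fold lower (adjusted p = 0.0269). The glutamate transporter gene Slc1a1 changed by -3.37 (SE 0.55, adjusted p = 0.0190), the chemokine gene Ccl25 by -3.23 (SE 0.37, adjusted p = 0.00908) and the protease inhibitor gene A2m by -3.07 (SE 0.43, adjusted p = 0.0140). The remaining 5 were Igsf5 (-3.31), Rbm24 (-3.17), Pramel19 (-3.17), the calcium pump gene Atp2b2 (-3.17) and the cadherin gene Cdh22 (-3.06), with adjusted p from 0.00985 to 0.0427. Of these, Igsf5, Rbm24, Atp2b2 and A2m were above background on 1 of 4 OHT arrays, and Pramel19 and Cdh22 on 2 of 4. A second probe of Atp2b2 fell less far (-1.73, adjusted p = 0.00469). The 20 genes moved the same way in each of the 3 lines, as the rule for naming genes required. Their calls depended on which line was left out. Of the 20, 5 passed without line cl5 (highest adjusted p = 0.182), 8 without line cl4 (0.137) and 14 without line cl6 (0.123). The 2abc lines enter the shared estimate of the spread: 17 passed without cl324.13 (0.0767), 19 without cl324.9 (0.0578) and 20 without cl280.4 (0.0379). St8sia3, Wnt8a, Gna14, Atoh1 and Mrgprd were those that passed without line cl5.

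In all, limma called 2797 of 22967 genes in 2ac, 1321 higher and 1476 lower, and each of the 2797 had the same sign in the 3 lines. A change of at least 2-fold was found for 1021 of them, 452 higher and 569 lower. The count was 149 without line cl5, 280 without line cl4, 1721 without line cl6, 1534 without cl324.9 and 1533 without cl324.13, and 3584 with the slide as the block. With the arrays scaled by their median, 2107 genes were called and the share of higher among them was 36.7%, against 47.2% with the 75th percentile. Control and OHT of line cl5 shared a slide, as did those of cl6, so their values per line are also values within a slide. The OHT value of line cl4 averages an array beside its control and an array on the slide of cl5. On the slide that line cl6 shared with the 2abc lines, limma called 0 genes for cl6, with 3781 at an unadjusted p under 0.05, where the lone line was assumed to vary like the 2abc lines.

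Several groups of genes fell in the 2ac lines. Genes of the 2-cell-embryo-like state, a rare state of ESC cultures, had the lowest median of the tested lists (-1.66): 7 of 14 fell and 0 rose over all genes tested, and the same numbers did when adjusted over the list alone. Tmem92 (-2.64, SE 0.31), Zscan4a (-1.94, SE 0.32), Zscan4c (-1.92, SE 0.32) and Zscan4f (-1.96, SE 0.34) were among them. The list passed camera (adjusted p = 0.000119, and adjusted p = 0.428 with an estimated correlation). Of 22 naive pluripotency genes, 7 fell and 0 rose (8 and 0 adjusted over the list alone), led by the transcription factor genes Tbx3 (-0.64, SE 0.09) and Tfcp2l1 (-0.55, SE 0.08), and by Fbxo15 (-0.80) and Jam2 (-0.63). Their median was -0.18 (camera adjusted p = 0.00325, and adjusted p = 0.355 with an estimated correlation). Of 24 germline genes, 6 fell and 0 rose (9 and 0 adjusted over the list alone), with the meiosis genes Sycp3 (-1.21, SE 0.08) and Stra8 (-2.74, SE 0.44), the helicase gene Ddx4 (-0.79) and Mov10l1 (-0.57, above background on 2 of 4 OHT arrays). Their median was -0.38 (adjusted p = 0.00915, and adjusted p = 0.598 with an estimated correlation). The lists of 21 mitosis genes, 27 genes of glycolysis and hypoxia and 23 DNA replication genes passed too. Of all genes tested 12.2% were called in 2ac, either way, and the called members of each of these lists were no larger a share. In mitosis, Kif20a (-0.37) and Aurka (-0.41) fell and 0 rose (1 and 0 adjusted over the list alone; median -0.19, adjusted p = 0.00325, and adjusted p = 0.428 with an estimated correlation). In replication, Orc1 (-0.58) and Mcm10 (-0.43) fell and 0 rose (1 and 0 adjusted over the list alone; median -0.14, adjusted p = 0.0102, and adjusted p = 0.294 with an estimated correlation). In glycolysis, Vegfa (-0.53), Car9 (-1.53, above background on 2 of 4 OHT arrays) and Hk1 (-0.57) fell and 0 rose, also when adjusted over the list alone (median -0.10, adjusted p = 0.0259, and adjusted p = 0.613 with an estimated correlation). By line (cl4, cl5 and cl6) the medians were -0.33, -0.31 and -0.04 (naive), -0.54, -0.49 and -0.08 (germline), -0.26, -0.21 and -0.05 (mitosis), -0.15, -0.19 and -0.08 (replication) and -0.26, -0.29 and 0.07 (glycolysis), so the glycolysis list was not lower in cl6. Without line cl5 the germline list had an adjusted p of 0.0587 (0.000141 to 0.0587 over its preset-camera alternatives) and the replication list 0.0561 (0.00274 to 0.0561). The glycolysis list had 0.0606 without cl280.4, 0.185 without line cl4 and 0.255 without line cl5 (0.000141 to 0.255) and lost its call under every other scaling. With fry the adjusted p was 0.0699 (germline), 0.0517 (2-cell-like), 0.0538 (mitosis) and 0.148 (glycolysis).

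Other groups rose in the 2ac lines. Of 24 p53 target genes, 9 rose and 1 fell (14 and 3 adjusted over the list alone), with a median of 0.42. Perp, a desmosome protein, rose by 2.27 (SE 0.11), the death receptor gene Fas at least 4.94-fold, Btg2 by 1.09 (SE 0.10) and Phlda3 by 0.65 (SE 0.12). The list had camera adjusted p = 0.000119, and adjusted p = 0.355 with an estimated correlation. Of 20 genes of the formative and primed epiblast, 6 rose and 0 fell (11 and 0 adjusted over the list alone; median 0.64). Besides Wnt8a these included the ephrin receptor gene Epha4 (1.61, SE 0.19), Sall2 (0.79) and the de novo DNA methyltransferase gene Dnmt3b (0.68), with camera adjusted p = 0.000119, and adjusted p = 0.294 with an estimated correlation. Of 16 neural genes 6 rose and 0 fell (6 and 1 adjusted over the list alone; median 0.42), including the transcription factor genes Pax6 (2.49, SE 0.24) and Neurod1 (3.01, SE 0.35) and the microtubule genes Map2 (2.13, SE 0.26) and Tubb3 (0.81). Pax6 and Map2 were above background on 1 of 3 control arrays. The test gave adjusted p = 0.000218, and adjusted p = 0.355 with an estimated correlation. Of 18 immediate targets of the ERK and Wnt pathways, on which the inhibitors of the medium act, 8 rose and 2 fell (10 and 3 adjusted over the list alone; median 0.61). The ERK feedback inhibitor gene Spry4 rose at least 2.79-fold, Phlda1 by 1.25 (SE 0.11) and the homeobox gene Cdx2 by 2.11 (SE 0.23, above background on 1 of 3 control arrays), while Tcf7, a mediator of Wnt signals, changed by -0.68. Its adjusted p was 0.00519, and adjusted p = 0.294 with an estimated correlation. Without line cl6 it was 0.0648, and without lines cl6 and cl280.4 it was 0.101 (0.000509 to 0.101 over its preset-camera alternatives). Of the 35 members of called lists that were among the 4 with the smallest p and passed in 2ac, 7 passed without line cl5, 9 without line cl4, 22 without line cl6, 28 without cl324.13, 30 without cl324.9 and 34 without cl280.4 (highest adjusted p = 0.183). Btg2, Fas, Perp, Spry4, Sycp3 and Wnt8a passed in each of these fits. Without the line as a block, Mov10l1, Zscan4f and Vegfa had adjusted p = 0.160, 0.0575 and 0.105. Leaving out genes of chromosomes 3 and X ended no list call in 2ac.

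The same comparison in the 2abc lines added the deletion of Jmjd2b. Wnt8a rose at least 8.0-fold (adjusted p = 0.00272), St8sia3 at least 5.21-fold (adjusted p = 0.00221), and Mc3r, a melanocortin receptor, at least 13.3-fold (adjusted p = 0.00408). Ly6a, a surface antigen of stem cells, rose at least 12.0-fold, the membrane glycoprotein gene Cd200 at least 4.13-fold, Tcim at least 4.03-fold and Aldh1a7 at least 2.64-fold (adjusted p = 0.0167, 0.00445, 0.00611 and 0.00531). Cox6a2, the muscle form of a cytochrome c oxidase subunit, rose by 4.45 (SE 0.78, adjusted p = 0.0186), Lrrk2 by 4.23 (SE 0.36, adjusted p = 0.00452) and Ccnd2 by 3.56 (SE 0.41, adjusted p = 0.00821), the last 2 above background on 2 of 3 control arrays. Of the genes that fell, Mrgprd was at least 6.46-fold lower (adjusted p = 0.00272). Slc1a1 changed by -4.13 (SE 0.55, adjusted p = 0.0103), Gc, the vitamin D binding protein, by -4.11 (SE 0.44, adjusted p = 0.0069), Stk33 by -3.92 (SE 0.46, adjusted p = 0.00856) and the collagen receptor gene Ddr2 by -3.84 (SE 0.55, adjusted p = 0.0120). The others were Ccl25 (-3.79), A2m (-3.52), the mesothelin gene Msln (-3.49), the X-linked amino acid transporter gene Slc38a5 (-3.49) and Smok3a (-3.46), with adjusted p from 0.0060 to 0.0126. Slc1a1, A2m, Slc38a5 and Smok3a were above background on 1 of 3 OHT arrays, and Ddr2 on 2 of 3. Second probes of Lrrk2 (4.20, adjusted p = 0.0179), Stk33 (-4.77, adjusted p = 0.0163) and Ddr2 (-3.93, adjusted p = 0.0198) passed as well. The 20 genes moved the same way in each of the 3 lines, again as the rule for naming genes required. Without line cl324.13, 7 of them passed (highest adjusted p = 0.115), and without cl324.9, 8 did (0.110). Wnt8a, Mc3r, Lrrk2, Cd200, St8sia3, Aldh1a7 and Mrgprd passed without cl324.13.

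In 2abc, limma called 4062 of 22967 genes, 2003 higher and 2059 lower, and 4061 of them had the same sign in the 3 lines. A change of at least 2-fold was found for 680 higher and 734 lower genes. The count was 215 without cl324.13, 231 without cl324.9, 2321 without 2ac line cl4 and 2349 without 2ac line cl5. Fitted on the slide that held all 3 lines with the 2abc arrays alone, 987 genes were called, 550 higher and 437 lower, and with the slide as the block in the fit of all samples 4627 were.

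The 2-cell-like genes also had the lowest median of the tested lists in 2abc (-1.67). Of 14, 9 fell and 0 rose (10 and 0 adjusted over the list alone), among them Tmem92 (-3.04, SE 0.31), Gm4340 (-2.50, SE 0.31), Eif1a (-0.53, SE 0.08) and Tcstv1 (-2.31, SE 0.40, above background on 2 of 3 OHT arrays). The list had camera adjusted p = 7.27e-05, and adjusted p = 0.449 with an estimated correlation. Its median was -0.69 in line cl280.4, against -2.09 in cl324.9 and -2.21 in cl324.13. Of 23 DNA replication genes, 11 fell and 0 rose (13 and 0 adjusted over the list alone; median -0.31), with the origin and helicase genes Orc1 (-0.93, SE 0.08), Mcm5 (-0.48) and Mcm10 (-0.51) and the cyclin gene Ccne1 (-0.53). The test gave adjusted p = 0.00102, and adjusted p = 0.362 with an estimated correlation. Of 22 naive pluripotency genes, 8 fell and 0 rose, also when adjusted over the list alone, with Tfcp2l1 (-0.56), Tbx3 (-0.47), Fbxo15 (-0.63) and the adhesion molecule gene Pecam1 (-1.13, SE 0.17). The median was -0.42 (adjusted p = 0.00631, and adjusted p = 0.416 with an estimated correlation). Of 20 core pluripotency genes, 5 fell and 0 rose (6 and 0 adjusted over the list alone; median -0.22), with Trim6 (-0.58), Tdgf1 (-0.49), Sall4 (-0.50) and Dppa4 (-0.56). That list had adjusted p = 0.00998, and adjusted p = 0.381 with an estimated correlation. Pou5f1, Sox2 and Nanog, named here after their values were seen, did not pass in either genotype (2ac 0.02, 0.18 and -0.22, 2abc -0.14, 0.16 and -0.22). Of 24 germline genes, 6 fell and 0 rose (7 and 0 adjusted over the list alone; median -0.31), with Mael (-1.59, SE 0.28), Rpl10l (-2.22, SE 0.42), Tuba3a (-2.13, SE 0.42) and the X-linked Tex11 (-0.92, SE 0.19), and with adjusted p = 0.00631, and adjusted p = 0.569 with an estimated correlation. By line (cl280.4, cl324.9 and cl324.13) the medians were -0.14, -0.48 and -0.52 (naive) and -0.10, -0.57 and -0.75 (germline). Without line cl280.4 the core pluripotency list had an adjusted p of 0.0634 (0.00312 to 0.0833 over its preset-camera alternatives). It was 0.0692 with cyclic loess normalisation and 0.0761 with the authors' deposited table.

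The regulators of silent chromatin were mixed in 2abc. Of 19 KRAB zinc-finger and retroelement-silencing genes, 6 fell and 2 rose (9 and 2 adjusted over the list alone; median -0.29), with Zfp961 (-1.23, SE 0.15), the HUSH subunit gene Tasor (-0.85, SE 0.13), Morc3 (-0.41) and Zfp809 (-0.64). The list had adjusted p = 0.0150, and adjusted p = 0.381 with an estimated correlation. Of 18 writers, erasers and readers of H3K9 methylation, 5 fell and 1 rose (8 and 1 adjusted over the list alone; median -0.21). Uhrf1 (-0.74, SE 0.07) and Hells (-0.63, SE 0.07), known for the maintenance of DNA methylation, and the heterochromatin protein gene Cbx1 (-0.67) fell, and the X-linked H3K9 methyltransferase gene Suv39h1 rose by 0.77 (SE 0.12). The test gave adjusted p = 0.0471, and adjusted p = 0.381 with an estimated correlation. Without line cl280.4 the zinc-finger list had an adjusted p of 0.112 (0.00447 to 0.112 over its preset-camera alternatives). The H3K9 list kept its call in 7 of 23 preset-camera alternatives (0.00499 to 0.280), with 0.0528 without the line as a block, 0.0512 with the slide as the block, and 0.173, 0.0577, 0.0619 and 0.0948 without lines cl280.4, cl4, cl5 and cl6. It also lost its call under every other scaling and with the authors' deposited table (0.102 to 0.146).

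Among the groups that rose in 2abc, 12 of 24 p53 targets did and 3 fell (18 and 4 adjusted over the list alone; median 0.49). Perp (1.90, SE 0.11) and Btg2 (1.15, SE 0.10) rose, and Aen (-0.74, SE 0.09) and Ei24 (-1.14, SE 0.16), both linked to cell death, fell. The test gave camera adjusted p = 7.27e-05, and adjusted p = 0.381 with an estimated correlation. Of 16 neural genes, 5 rose and 1 fell (7 and 1 adjusted over the list alone; median 0.39). Pax6 rose at least 3.41-fold, Neurod1 by 2.77 (SE 0.35), Map2 by 1.97 (SE 0.26, above background on 1 of 3 control arrays) and Sox11 by 1.46 (SE 0.20), with adjusted p = 0.00287, and adjusted p = 0.381 with an estimated correlation. Of 24 genes of the ATF4 response to amino acid and endoplasmic reticulum stress, 7 rose and 1 fell (8 and 1 adjusted over the list alone; median 0.29). The stress transcription factor genes Atf3 (0.80, SE 0.09) and Ddit3 (1.38, SE 0.17) and the lipoprotein receptor gene Vldlr (1.15, SE 0.22) rose and the serine pathway gene Shmt2 fell (-0.47), with adjusted p = 0.00287, and adjusted p = 0.569 with an estimated correlation. The ATF4 median was 0.47 in cl324.9 and 0.52 in cl324.13, and -0.07 in cl280.4. The sterol median was 0.32, 0.23 and 0.05 in these lines. Of 24 imprinted genes, 9 rose and 1 fell (9 and 2 adjusted over the list alone; median 0.43), with Magel2 (0.93), Mest (0.75), Mirg (1.38) and Peg3 (1.01), and with adjusted p = 0.00631, and adjusted p = 0.381 with an estimated correlation. Of 25 sterol synthesis genes 3 rose and 1 fell (5 and 1 adjusted over the list alone; median 0.19). Among them Stard4 rose by 0.61 and Sc5d by 0.51, while the early pathway enzyme gene Hmgcs1 changed by -1.82 (SE 0.18). The list had adjusted p = 0.00995, and adjusted p = 0.569 with an estimated correlation. Of all genes tested 17.7% were called in 2abc, and the called sterol genes were no larger a share. Of 17 Hox genes, 6 rose and 0 fell, also when adjusted over the list alone (median 0.41), among them Hoxa7 (1.11, SE 0.20), Hoxa3 (1.56, SE 0.31) and Hoxd8 (0.97, SE 0.20), and with adjusted p = 0.0153, and adjusted p = 0.580 with an estimated correlation. Without line cl280.4 the Hox list had an adjusted p of 0.334 (0.00336 to 0.334 over its preset-camera alternatives), and without cl324.9 the sterol list had 0.118 (0.00185 to 0.118). With the authors' deposited table the imprinted list had 0.111 (0.00251 to 0.111). With fry the ATF4, sterol and germline lists had 0.0932 each and the Hox list 0.1405. Of the 52 members of called lists that were among the 4 with the smallest p and passed in 2abc, 4 passed without cl324.9 (Btg2, Orc1, Pax6 and Perp), 5 without cl324.13, 45 without line cl4, 45 without line cl5, 48 without cl280.4 and 52 without line cl6 (highest adjusted p = 0.168). Without the line as a block, Mest had adjusted p = 0.106. Leaving out genes of chromosomes 3 and X ended no list call in 2abc.

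**Figure D3:**
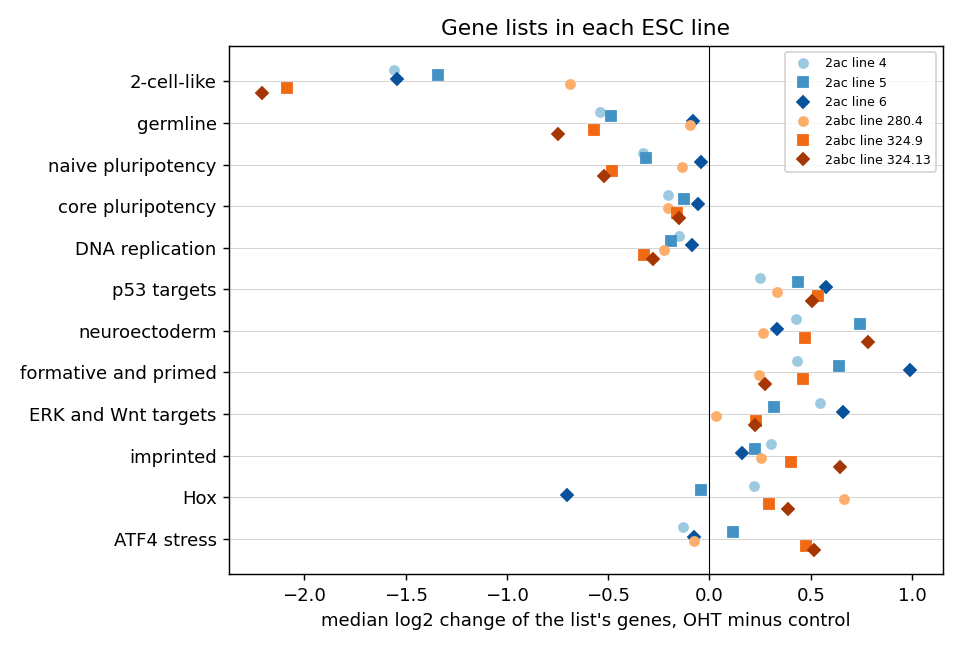
Median log2 change (OHT minus control) over the measured genes of 12 gene lists, with 1 point per ESC line. The 2-cell-like list lies below 0 in all 6 lines (-2.21 to -0.69) and the p53 target list above 0 in all 6 (0.25 to 0.58), while the Hox list lies between 0.29 and 0.67 in the 2abc lines and at 0.22, -0.04 and -0.70 in 2ac lines cl4, cl5 and cl6.

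The mean OHT effect over the 6 lines was tested next. St8sia3 (adjusted p = 0.000108), Wnt8a (0.000536), Mc3r (0.000767), Cd200 (0.000985), Aldh1a7 (0.0010) and Tcim (0.00116) rose, with folds that are bounds in at least 1 genotype. Of the named genes with a fitted value, Lrrk2 (3.86, SE 0.26, adjusted p = 0.0010), Ccnd2 (3.75, SE 0.29, adjusted p = 0.00126), Gna14 (3.64, SE 0.19, adjusted p = 0.00068) and Insm1 (3.51, SE 0.35, adjusted p = 0.00239) rose. Mrgprd fell (adjusted p = 0.000536), with a fold that is a bound in both genotypes. Among the named genes with a fitted value, Slc1a1 (-3.75, SE 0.39), Ccl25 (-3.51, SE 0.26), A2m (-3.30, SE 0.30) and Gc (-3.25, SE 0.31) fell, as did Ddr2 (-3.19), Kdm4c (-3.06), Stk33 (-3.05), Igsf5 (-3.02) and Mslnl (-3.01), with adjusted p from 0.00073 to 0.0105. Mslnl, A2m and Igsf5 were above background on 1 OHT array in each genotype, and in 2abc Slc1a1 was so on 1 OHT array and Ddr2 on 2. Of the 3 control arrays of each genotype, Gna14 was above background on 1 and Ccnd2 on 2. Lrrk2 was so on 2 of 3 control arrays in 2abc, and Insm1 on 2 of 3 in 2ac. A second probe of Lrrk2 rose by 3.03 (adjusted p = 0.00931). The 20 genes passed with each line left out in turn (highest adjusted p = 0.0428). In all, 6552 of 22967 genes were called, 3201 higher and 3351 lower, of which 5544 (84.6%) had the same sign in all 6 lines and 1395 changed at least 2-fold (557 higher and 838 lower). The count was 3546 without cl324.13, 3619 without line cl5, 3659 without cl324.9 and 4108 without line cl4, and 7108 with the slide as the block.

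The tests over 6 lines called 14 lists. The 2-cell-like genes fell (10 of 14 and 0 up, 11 and 0 adjusted over the list alone; median -1.81, adjusted p = 4.93e-05, and adjusted p = 0.339 with an estimated correlation), with Tmem92 at -2.84 (SE 0.22). Of the p53 targets 17 rose and 3 fell (19 and 3 adjusted over the list alone; median 0.45, adjusted p = 4.93e-05), of the neural genes 9 rose and 1 fell (10 and 1; median 0.51, adjusted p = 0.000595) and of the formative and primed genes 10 rose and 1 fell (10 and 1; median 0.57, adjusted p = 0.0101), each with adjusted p = 0.273 with an estimated correlation. Of the naive genes 10 of 22 fell and 0 rose (10 and 0 adjusted over the list alone; median -0.26, adjusted p = 0.00161), of the core pluripotency genes 6 of 20 fell and 0 rose (8 and 0; median -0.18, adjusted p = 0.0324) and of the replication genes 12 of 23 fell and 0 rose (14 and 0; median -0.23, adjusted p = 0.00161), again each with adjusted p = 0.273 with an estimated correlation. The zinc-finger genes (7 down and 2 up, 9 and 2 adjusted over the list alone; median -0.21, adjusted p = 0.0172) and the ERK and Wnt targets (8 up and 3 down, also adjusted over the list alone; median 0.26, adjusted p = 0.0209) had adjusted p = 0.273 with an estimated correlation as well. The germline genes (11 down and 0 up, 12 and 0 adjusted over the list alone; median -0.36, adjusted p = 0.00466) and the mitosis genes (4 down and 0 up, 3 and 0 adjusted over the list alone; median -0.12, adjusted p = 0.0208) had adjusted p = 0.556 with an estimated correlation. The imprinted genes (11 up and 2 down, 11 and 5 adjusted over the list alone; median 0.34, adjusted p = 0.0158) had adjusted p = 0.311 with an estimated correlation, the sterol genes (7 up and 1 down, 8 and 1 adjusted over the list alone; median 0.15, adjusted p = 0.0158) had adjusted p = 0.60 with an estimated correlation, and the glycolysis genes (5 down and 1 up, 9 and 1 adjusted over the list alone; median -0.16, adjusted p = 0.0409) had adjusted p = 0.657 with an estimated correlation. Of all genes tested 28.5% were called over the 6 lines, and the called mitosis and glycolysis genes were no larger a share. The mitosis median was 0.01 in cl324.9 and in cl324.13, and the glycolysis median 0.07 in cl6, while the other 12 lists had medians of the same sign in all 6 lines.

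Besides the estimated correlation, other alternatives ended 8 of these calls over 6 lines. Without line cl280.4 the adjusted p was 0.0801 for core pluripotency, 0.155 for mitosis, 0.247 for glycolysis and 0.0538 for the zinc-finger genes. Without line cl4 it was 0.0663 for core pluripotency, 0.0663 for mitosis and 0.126 for glycolysis, and without line cl5 it was 0.0691, 0.0519 and 0.123. Without line cl6 it was 0.0654 for the formative and primed genes, 0.136 for the sterol genes and 0.110 for the ERK and Wnt targets, and without cl324.9 it was 0.0539 for these targets. The authors' deposited table gave 0.138 for the imprinted genes and 0.161 for the ERK and Wnt targets. The core pluripotency, mitosis and glycolysis calls were lost under every other scaling and with that table. Their adjusted p there was 0.0549 to 0.130, 0.0639 to 0.0929 and 0.0962 to 0.301. With the line as a random block the adjusted p was 0.0502 for core pluripotency, 0.0808 for glycolysis and 0.0757 for the sterol genes. With fry it was 0.0813 for glycolysis and 0.0579 for the sterol genes. The ranges over all preset-camera alternatives were 0.0130 to 0.130 (core), 0.00304 to 0.155 (mitosis), 0.00113 to 0.301 (glycolysis), 0.00304 to 0.0538 (zinc finger), 0.00116 to 0.0654 (formative and primed), 0.0033 to 0.136 (sterol), 0.00645 to 0.161 (ERK and Wnt) and 0.00507 to 0.138 (imprinted). Of the 56 members among the 4 with the smallest p of a called list that passed over 6 lines, 48 passed without cl324.13, 51 without cl324.9, cl4 or cl5, 55 without cl280.4 and 56 without cl6 (highest adjusted p = 0.143).

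Whether the effect differed between genotypes was tested as the 2abc effect minus the 2ac effect. The difference was smallest in p for Vrtn (-2.25, SE 0.15, adjusted p = 0.123), followed by Osbpl6 (1.56), Lbh (1.44), Sema4g (1.32) and Inca1 (1.20), each with adjusted p = 0.288, and none of them passed. In 2ac, Osbpl6 was above background on 1 of 4 OHT arrays and Lbh and Inca1 on 2 of 4. For Kdm4b, deleted in 2abc alone, the difference was -2.34 (SE 0.26, adjusted p = 0.288 over all genes), and it was the 1 of the 3 measured Jmjd2 genes that passed when adjusted over that list alone. The difference was 0.07 for Kdm4a (adjusted p = 0.885) and -0.31 for Kdm4c (adjusted p = 0.786). With the line as a random block Kdm4b was the 1 gene called (adjusted p = 0.0418), and in none of the other alternatives did it pass (range 0.0418 to 0.722). With the line as a fixed block limma called 0 of 22967 genes, with 2516 at an unadjusted p under 0.05 where 1148.4 would be so without any difference. On the slide that held all 2abc lines, 2ac was line cl6 alone, which has no spread of its own. The 0 called there, with 2592 at an unadjusted p under 0.05, takes that line to vary as the 2abc lines do and decides nothing.

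Across genes the effects of both genotypes correlated (Pearson r = 0.740, Spearman 0.627), and 71.7% of genes had the same sign in both. Genes are not independent replicates, and no sample entered both effects. The correlation of single lines across genotypes was 0.434 to 0.636, and that of lines within a genotype 0.527 to 0.752. By line, the changes of 2ac lines cl4, cl5 and cl6 correlated with the mean 2abc change at 0.669, 0.693 and 0.547, line cl6 being the one on the 2abc slide. Both comparisons called 845 genes as higher and 878 as lower, where independent lists would share 115 and 132, and 2 and 8 in opposite directions, where independent lists would share 118 and 129. Both tests used the same estimate of the spread of a gene, which by itself can raise the overlap. Independent lists are therefore a low baseline for it.

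**Figure D4:**
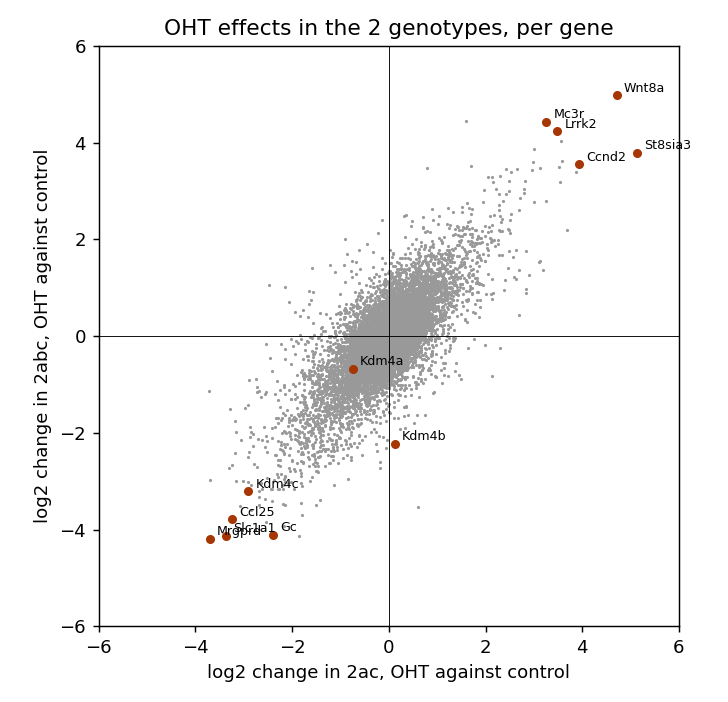
Log2 change (OHT against control) of each of 22967 genes in the 2ac lines (horizontal axis) and in the 2abc lines (vertical axis), with 12 genes named. The effects correlate across genes (r = 0.740), and Kdm4b lies near 0 in 2ac (0.12) and at -2.23 in 2abc; for Wnt8a, St8sia3 and Mrgprd on both axes, and for Mc3r on the vertical axis, the position is the measured signal, of which the fold is a bound only.

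Some lists nonetheless differed between genotypes under camera. The ATF4 genes were higher in 2abc than in 2ac (median difference 0.28, adjusted p = 2.35e-05, and adjusted p = 0.675 with an estimated correlation), led by Atf3 (0.90, SE 0.13), Ddit3 (1.12, SE 0.24), Vldlr (1.19, SE 0.31) and Nupr1 (1.05, SE 0.29), with 0 genes passing over all genes and 2 up when adjusted over the list alone. The Hox genes were higher too (median difference 0.55, adjusted p = 0.00132, and adjusted p = 0.675 with an estimated correlation), with 0 passing either way and with Hoxd8 (1.17, SE 0.28) first in p. The formative and primed genes (median difference -0.41, adjusted p = 0.0367), the ERK and Wnt targets (-0.21, adjusted p = 0.0392) and the replication genes (-0.14, adjusted p = 0.0484) were lower in 2abc, each with adjusted p = 0.609 with an estimated correlation, and with 0 genes passing over all genes and 1, 2 and 0 down when adjusted over the list alone. Over all 22967 genes limma called 0 as well at the same threshold. In these differences Dnmt3b (-1.15, SE 0.16), Epha4 (-1.08, SE 0.27), Myc (-1.51, SE 0.28) and Mcm5 (-0.37, SE 0.11) had the smallest p of their lists or were next to it. The ATF4 call was kept in all 22 preset-camera alternatives (3.80e-09 to 0.0024). With fry the ATF4 list had an adjusted p of 0.365, the Hox list 0.554, and the formative and primed and the ERK and Wnt lists 0.0648 each. The Hox call had an adjusted p of 0.163 without cl280.4 (3.27e-05 to 0.299 over its preset-camera alternatives). The formative and primed call had 0.0949 without cl280.4, 0.0521 without cl324.13 and 0.228 without line cl6 (0.00272 to 0.469), and the ERK and Wnt call 0.348 without cl280.4 and 0.206 without line cl6 (0.00272 to 0.778). The replication call was kept in 3 of 22 preset-camera alternatives (0.0107 to 0.356), with 0.151 without cl280.4, 0.0697 without cl324.9, 0.0521 without cl324.13, 0.0510 without line cl4 and 0.206 without line cl6. It was also lost under every other scaling and with the authors' deposited table (0.120 to 0.257). With the genes of chromosomes 3 and X left out, the formative and primed, ERK and Wnt, and replication lists had 0.0560, 0.0542 and 0.0635. With no block for the line the ERK and Wnt list had 0.219 and the replication list 0.0760, and with the line as a random block 0.122 and 0.0790.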

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

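The tests of chromosome 3, the X chromosome and line cl280.4 in this part were chosen after the results they address had been seen, and the regroupings of samples were fixed before.

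For 2 genes the value of 1 line lay far from those of the other 5. For Wnt8a it was 3.82 in 2ac line cl6 and 4.93 to 5.22 in the others, but Wnt8a was above background on 0 control arrays, so this gap rests on unmeasured signal and does not show that cl6 stands apart. Ccnd2 changed by 2.16 in 2abc line cl280.4 and by 3.90 to 4.26 in the others, and was above background on 2 of 3 control arrays of each genotype. Of 49 sets of 6 lines looked at with Dixon's test these 2 lay beyond its 95% limit, where chance gives about 1 in 20 (2.45 expected).

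A further 5 gene lists stood out because the 2abc effect differed from the 2ac effect by camera at its preset correlation, and none did with an estimated one (adjusted p = 0.609 to 0.675). The Hox list had a median difference of 0.55, with 0.67, 0.29 and 0.39 in 2abc lines cl280.4, cl324.9 and cl324.13 and 0.22, -0.04 and -0.70 in 2ac lines cl4, cl5 and cl6. The ATF4 list had 0.28 (-0.07, 0.47 and 0.52 against -0.13, 0.12 and -0.08), with 3 of its members on chromosome 3 (Phgdh, Cth and Sars) and Slc7a3 on the X chromosome. The formative and primed list had -0.41 (0.25, 0.46 and 0.27 against 0.43, 0.64 and 0.99), with Lef1 and Car14 on chromosome 3 and Sox3 on the X chromosome. The ERK and Wnt list had -0.21 (0.03, 0.23 and 0.22 against 0.54, 0.32 and 0.66), with Spry1 on chromosome 3. The DNA replication list had -0.14 (-0.22, -0.33 and -0.28 against -0.15, -0.19 and -0.08), with Pola1 on the X chromosome.

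Whether the counts of called genes could come from any grouping of the samples was tested by refitting other groupings. In 2ac the real split called 2797 genes and the highest other split 0, and in 2abc these were 4062 and 9. In each case 1 of 10 splits reached the real count, the real one, and 10 splits are too few for a share under 0.05. Over the 6 lines, 1 of 32 ways to part the 6 pairs reached the real count of 6552, the real one, with 1 gene in the highest other, and 1 of 100 splits of the 12 samples, the real one and 99 drawn at random, reached the 6019 of a fit with a single coefficient. The highest other had 2176 genes and parted 4 pairs, all as in the real split, and 5 drawn splits could not be fitted. Grouping by chance therefore does not account for the count over 6 lines. For the difference between genotypes 10 of 10 splits of the lines reached the real count, which was 0, as was the highest other. Every split reaches a count of 0, so this decides nothing.

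Genes of chromosome 3 were higher after OHT in all 6 lines. A few strongly changed genes would not account for it, since 81.2% of its genes lay above the median change of the other autosomes, though this test replaced a first version after its value was seen. Dim probes or scaling would not either, as the shift was 0.28 in the brightest genes after quantile normalisation. An extra copy of chromosome 3 in part of the OHT cells could do so: all 5 blocks of neighbouring genes were shifted, by 0.14 to 0.35. Relative to other autosomes, chromosome 3 stood at -0.10 to 0.08 in the controls and at 0.02, 0.43, 0.41, 0.16, 0.31 and 0.31 in the OHT samples of cl280.4, cl324.9, cl324.13, cl4, cl5 and cl6, and DNA copy number was not measured here, so a change of expression along the chromosome that follows from the deletions was not tested and stays open.

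X-linked genes were higher after OHT in 2ac line cl6 only by value, the difference from other lines not being tested. Dim probes or scaling would not account for it, as the shift was 0.71 in the brightest genes after quantile normalisation. An X copy number that differs between both cultures of an XX line could: the lowest of 5 blocks of neighbouring X genes was shifted by 0.65, and 0 of the readings of 5 Y probes on its 2 arrays lay above background, against 4 to 11 readings in each other line. Relative to autosomes, X genes stood at 0.15 in its control and 0.89 in its OHT sample, and at -0.04 to 0.07 in the other lines. Reactivation of an X chromosome is a biological explanation that was not tested.

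Line cl280.4 had smaller changes than the other lines. The targeted genes gave no sign of a less complete deletion in its OHT culture. The larger shortfall of its falls of Kdm4b and Kdm4c, against the smaller fall of the other 2abc lines, was -0.0543, a fall at least as large. Kdm4a changed by -0.87 in cl280.4 and by -0.54 and -0.60 in cl324.9 and cl324.13. The position of the probes relative to the deleted exons is not given, so remaining intact transcript was not measured. Compressed signal on its arrays was not decided. Its slope on the other 2abc lines was 0.474 among the brightest genes after quantile normalisation. Such a slope is also lowered, without compression, where the changes of lines correlate weakly. The slopes of cl4 and cl6 on the other 2ac lines were 0.765 and 0.766 there. Its changes correlated at 0.636, 0.605 and 0.434 with those of 2ac lines cl4, cl5 and cl6 and at 0.530 and 0.576 with those of cl324.9 and cl324.13. No biological explanation was tested.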

How the results depend on the processing

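The effect correlation stayed positive, the count of genes that differ between genotypes stayed at 0 except with a random block, and no named gene or list with a call turned its direction. Of all genes called, 1 in 2ac, 1 in 2abc and 2 over 6 lines changed sign with normexp, and 1 in 2ac and 1 over 6 lines with the authors' deposited table. The 3 lines per genotype limit the tests, and signal over background limits what can be said of dim genes, as 50.1 to 63.9% of probes were well above background per array. No line without floxed alleles was analysed with OHT here, so effects of OHT and of Cre were not separated from those of the deletions. The labels give control and OHT cultures the same days of treatment and of culture after it. Why a count or call moved below was not tested, also where a trait of the setting is given beside it.

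With the line as a random block, which leaves more residual degrees of freedom, 4582 genes were called in 2ac and 1 in the difference. This ended 6 list calls. They were glycolysis in 2ac and over 6 lines, core pluripotency and sterol over 6 lines, and replication and ERK and Wnt in the difference. Without a block for the line, and so without the pairing, the counts were 3042, 4184, 6462 and 0 (2ac, 2abc, 6 lines, difference), 39 list calls and r = 0.741. This ended the calls of the H3K9 list in 2abc and of the replication and ERK and Wnt lists in the difference, moved 7 named list members across the threshold (Tdgf1, Mov10l1, Zscan4f, Vegfa and Rif1 in 2ac, Mest in 2abc, Cdk1 over 6 lines) and changed no other call of a list or named list member. Without the filter on dim probes, which tests more genes, the counts were 884, 1521 and 4337 and r = 0.520. With only both groups of a comparison, and so fewer samples, they were 1583 in 2ac and 987 in 2abc, and with array weights 5821 and 7342. A change of at least 2-fold left 1021, 1414 and 1395, and an adjusted p under 0.1 gave 4740 in 2ac and 6283 in 2abc. With lines cl6 and cl280.4 left out, a setting chosen after seeing the data, 6448 genes were called in 2abc. With an estimated correlation 0 of 42 list calls were left.

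Leave-one-out gave 149 to 3441 genes in 2ac, 215 to 4702 in 2abc, 3546 to 6691 over 6 lines and 0 in the difference, r of 0.691 to 0.736 and 33 to 42 list calls. Normexp on mean spot intensities was not run, and on median intensities, added after seeing the data, it gave 3805, 4785, 7172 and 0. The authors' deposited table gave 3623, 4586, 6215 and 0, with r = 0.792 and 34 list calls. Without the genes of chromosomes 3 and X, also added after seeing the data, it was 2629, 3811, 6117 and 0, with 41 list calls. Over all alternatives, list tests kept their side of the threshold 2287 times, gained a call 83 times and lost it 174 times. For named genes this was 5377, 49 and 522, and for the targeted genes 297, 1 and 8. Medians of the ribosomal protein and reference lists changed sign with other scalings, and none of these passed.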

Other observations

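Genes of other lineages were mixed, and their lists did not pass in camera at its preset correlation. Of 13 mesoderm genes, 3 rose and 0 fell in 2ac (4 and 2 adjusted over the list alone, camera adjusted p = 0.260): the signalling gene Bmp4 (2.63, SE 0.19, adjusted p = 0.00424), Evx1 (2.38, above background on 2 of 3 control arrays) and Twist1 (1.09, above background on 2 of 3 control arrays). In 2abc Bmp4 rose by 1.18 (adjusted p = 0.0151) and no other did (list adjusted p = 0.766). Of 17 endoderm genes, 3 rose and 3 fell in 2ac (adjusted p = 0.0628), with the laminin genes Lama1 (-0.72) and Lamb1 (-0.84) lower, Cubn at least 5.31-fold higher and the collagen chaperone gene Serpinh1 higher (1.21). In 2abc 2 rose and 3 fell (adjusted p = 0.198), with Serpinh1 (1.48) and Gata6 (0.88) higher and Sox7 (-1.94, above background on 1 of 3 OHT arrays) and Lamb1 (-0.61) lower. Of 18 trophectoderm genes, Cdx2 (2.11) and the X-linked Rhox6 (2.20) and Rhox9 (1.75) rose in 2ac and Krt7 fell (-1.76; list adjusted p = 0.538). In 2abc Rhox6 (1.85) and Rhox9 (1.39) rose and Ascl2 (-1.52) and Gata2 (-1.33) fell (list adjusted p = 0.540). Of 12 interferon-response genes, the RNA sensor gene Ddx58 (1.27, adjusted p = 0.00544), Ifi27l2a (2.43) and Cxcl10 (at least 4.74-fold) rose in 2ac and Stat2 fell (-0.76), and in 2abc Ifi27l2a (3.45) and Bst2 (0.54) rose and Xaf1 fell (-1.77), with list adjusted p = 0.635 and 0.544. Ifi27l2a was above background on 1 of 3 control arrays in each genotype. Over the 6 lines the adjusted p was 0.428 (mesoderm), 0.0523 (endoderm), 0.428 (trophectoderm) and 0.518 (interferon). Members of lists without a call were not refitted with lines left out.

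Of 14 genes for H3K36 methylation, the demethylase gene Kdm2b fell in both genotypes (-0.55, adjusted p = 0.0313, and -0.95, adjusted p = 0.00804), and in 2abc Mtf2 fell (-0.50) and Nsd2 (0.59) and Phf19 (0.62) rose. The list had adjusted p = 0.738 in 2ac, 0.835 in 2abc and 0.971 over 6 lines. In 2ac, where their lists did not pass, the imprinted genes Mest (1.18, adjusted p = 0.00643), Cdkn1c (1.16), Peg3 (0.78) and Magel2 (0.65) rose, Hmgcs1 fell (-1.52), Tdgf1 fell (-0.40, with adjusted p = 0.0680 without the line as a block), Zfp961 (-0.95), Zfp809 (-0.58) and Morc3 (-0.31) fell, and of the H3K9 genes Suv39h1 rose (0.82) while Hells (-0.49), Uhrf1 (-0.46) and Kdm1a (-0.35) fell. These lists had adjusted p = 0.108 (imprinted), 0.0784 (sterol), 0.176 (core pluripotency), 0.0745 (zinc finger) and 0.148 (H3K9). The ATF4 and Hox lists had 0.674 and 0.779 in 2ac, the latter with a median of -0.19 that was positive without line cl6 (0.09). In 2abc the formative and primed, ERK and Wnt, mitosis and glycolysis lists had 0.140, 0.196, 0.319 and 0.236. Over the 6 lines the H3K9, ATF4 and Hox lists had 0.0521, 0.0523 and 0.220. With fry, 10 lists that did not pass in camera had an adjusted p under 0.05. These were the H3K9 (0.00355), endoderm (0.0160) and zinc-finger lists (0.0102) in 2ac, and the formative and primed (0.0296), ERK and Wnt (0.0417), endoderm (0.0487) and interferon lists (0.0487) in 2abc. Over the 6 lines they were the H3K9 (0.000351), endoderm (0.00714) and interferon lists (0.00485).

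Ribosomal protein genes (22) held 0 passing genes in either genotype (adjusted p = 0.282 and 0.110, medians -0.02 and -0.10). Of 12 reference genes, 2 fell in 2ac, B2m (-0.54) among them, and 1 in 2abc (list adjusted p = 0.738 and 0.634). Of 12 fibroblast markers, Mmp2 (-0.92) and Pdgfrb fell in 2ac, and in 2abc Cdh11 fell (-1.99, above background on 1 of 3 OHT arrays) and Col1a2 rose (1.16), with list adjusted p = 0.627 and 0.540. Of 6 blood cell markers 0 passed in 2ac and Cd3e fell in 2abc (-0.88), with 0.749 and 0.634. Line cl6 had no signal of the Y-linked Eif2s3y and Ddx3y above background in either culture, so no test over the 6 lines is given for them. In cl280.4, cl324.9, cl324.13, cl4 and cl5 the log2 change was -1.06, -1.13, -0.99, -1.63 and -1.67 for Eif2s3y and -0.71, -0.16, -0.33, -0.40 and -0.51 for Ddx3y. Median, mean and test differed in sign for fibroblast (0.15, -0.34, down) and interferon genes (-0.01, 0.37, up) in 2ac, and for mesoderm (0.01, -0.01, up) and H3K36 genes (-0.01, 0.01, up) in 2abc. They also did for H3K36 genes in 2ac (0.01, -0.03, down), for H3K36 (0.02, -0.01, down) and blood cell genes (0.04, -0.05, down) over the 6 lines, and in the difference for the germline (-0.19, -0.11, up), naive (-0.04, -0.07, up), fibroblast (-0.07, -0.02, up), interferon (-0.09, -0.15, up) and endoderm lists (0.09, -0.03, up).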
